A study of Caenorhabditis elegans with 2 samples.

How the data were processed

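The series holds chromatin immunoprecipitation followed by sequencing (ChIP-seq) of the C. elegans protein MADF-9, done on whole worms at the L4 larval stage, 48 hours after starved L1 larvae were released. Per the labels, the worms carried an insertion of TY1, EGFP and 3xFLAG tags at madf-9 on chromosome IV, the antibody was directed against GFP, and chromatin was sonicated to 200 to 800 bp. There was 1 group with 2 biological replicates. No other group was described, and the control library was not analysed here, so no comparison of conditions was possible. The labels number the replicates as biological, and nothing else says how the cultures were kept apart.

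The authors deposited peak lists on the ce11 assembly, per the labels, and no read counts, so the sequencing depth of each replicate is unknown. Each list came as all ranked regions and as a thresholded set. The peak caller, the aligner and their versions are not given in the sources used here. The deposited score of each peak is a scaled value of the irreproducible discovery rate (IDR), the estimated share of regions that do not recur between the inputs of a run, and the deposited score was at least 830 in the thresholded set used here, which is an IDR of at most 0.01. The deposited signal of each peak is the caller's own strength value on a scale that is not stated, and it is used below to describe and rank peaks within a list, to compare groups of peaks of the same list by median or by mean log2 value, and to correlate the replicates over the same peaks. The deposited −log10 q values were read, and the deposited −log10 IDR values, which stop at 5, were used to find which ranked regions pass. The authors ran the IDR step per replicate and on both replicates together. In the ranked list behind the main set, 39691 input intervals matched replicate 1 regions and none replicate 2 regions on one side, while 45388 matched replicate 2 regions on the other, so that set compares the replicates. The other series set has pooled data whose inputs are not the replicates.

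Signal values of peaks in the main set are the authors' pooled values, with no error of their own. The signal of each replicate at a main peak was taken from the region of that replicate's own ranked list with the largest overlap of at least 1 bp. Genes came from Ensembl release 115 on WBcel235, the assembly that ce11 names, and sequence from the RefSeq copy of the same assembly. Every peak ended within its reference chromosome. Coordinates are 1-based on ce11.

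A promoter was taken from 1000 bp upstream to 200 bp downstream of an annotated transcript start of a protein-coding gene, and a gene with a summit in that window is called bound. Shares of summits were tested against 10000 random placements on the same chromosomes, two-sided, where 0.0002 is the smallest p the draws can give. Shared peaks were tested against 1000 placements, one-sided, with a smallest p of 0.001. Chromosome counts were tested with 10000 multinomial draws. Placements for shares of summits were binomial draws per chromosome, with summits taken as independent. No values were permuted in these tests. Where a permutation p is given below for shares of summits, shared peaks or chromosome counts, it comes from these draws or placements. Correlations and differences of medians used 100000 permutations, with a smallest p of 1e-05. Gene lists were fixed as gene classes and tested with Fisher's exact test, two-sided, over the 10896 protein-coding genes that have a class symbol. Words of 8 bases within 50 bp of the summit were set against flanks 150 to 200 bp away, found on chromosomes I, III and V and tested on II, IV and X with Fisher's exact test. Centres and flanks belong to the same summits, and the test ignores this pairing. The centre holds 94 word positions and the flanks 86, a ratio of 1.09 that chance alone gives if both have the same base composition. No control for base composition was run. P-values in a family were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Shares carry 95% Wilson intervals, which cover counting error only, and the limit given for a count of 0 is 3 counts of the total.

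Genes were named by a fixed rule: madf-9 with any peak within 5 kb, the 10 peaks with the highest signal, up to 4 bound members with the highest signal of each list past the threshold or with at least 2 bound members, every bound MADF family member, and the 3 strongest peaks outside promoters. From the lists that did not pass the threshold, only some of these members are named. The tests, lists, naming rule and most alternatives were set before the data were examined. The reading of "with a symbol" as a class symbol, and a further set of alternatives that leave out peaks near tRNA genes, change the IDR threshold, the partner set or the gene background, or test the same words in other sets, were chosen after seeing the data. Alternatives covered the other peak set, stricter sets, each replicate's own set, other windows, distances, backgrounds, word lengths and statistics.

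The tests were also tested on simulated data. This was added after they had been run once on the deposited lists, and they were then run again. With lists of the real sizes planted at a higher binding rate among 19973 genes, 98.8% of planted lists were called and 0.750% of the others. The real test used the 10896 genes with a class symbol. Binding was planted at a single high rate and independently for each gene. The simulation therefore does not say how often weaker lists, or lists whose genes share summits, would be called. A planted word in 1600 simulated peaks led the words and passed on the test chromosomes. A shared share of 70 percent was recovered as 70.3% over 800 simulated intervals. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.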

Results

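Binding of GFP-tagged MADF-9, a protein of a family named for its MADF domain, a DNA-binding fold related to Myb, was mapped in whole L4 larvae of C. elegans in 2 biological replicates. The set called between the replicates held 1637 peaks with a median width of 260 bp, drawn from 86867 ranked regions. Replicate 1 alone gave 1002 peaks and replicate 2 alone gave 806, a ratio of 1.24. The pooled set held 1632 peaks, of which 1371 had the same interval as a peak of the set between replicates. The depth of the libraries is unknown. The peak signal, the authors' own value per peak, had a median of 89.3 and reached 1259 in the set between replicates.

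The promoter of madf-9 itself carried a peak. It spans 3636494 to 3636927 on chromosome IV (ce11), and its summit lies 279 bp upstream of the start of madf-9 (WBGene00022608, chromosome IV, 3637079 to 3640466, plus strand). Its signal of 307 ranked 35 in the set, with 175 in replicate 1 and 125 in replicate 2. It was the 1 passing region of 17 ranked regions within 5 kb of the gene, and the other 16 had signals from 4.58 to 54.1. The promoter of madf-11 (WBGene00015468), of the same family, held a summit 280 bp upstream of its start on chromosome III with a signal of 84.2. These were the 2 bound genes among the 10 MADF family members, an odds ratio of 3.98 (95% interval 0.410 to 19.97) that did not pass Fisher's exact test, two-sided (adjusted p = 0.213).

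The strongest peaks lay at lin-42, mog-4, tasp-1 and rpl-3. The highest, with a signal of 1259, lies on chromosome II from 1246891 to 1247276, inside an intron of lin-42, the worm homologue of the period genes that acts in developmental timing, and 3086 bp upstream of the nearest start. An annotated noncoding RNA gene, F47F6.15, also covers the summit. In the replicates' own lists it had signals of 690 and 523. The promoter peak of mog-4, which encodes a DEAH-box helicase of the splicing machinery, had a signal of 609 at 251 bp upstream of the start (chromosome II, 14561751 to 14561964). The peak at tasp-1 and K01G5.10 reached 598 (chromosome III, 10759140 to 10759365), and that of rpl-3, a protein of the large ribosomal subunit, reached 584 (chromosome III, 3867471 to 3867672). The promoters of rpl-15 with K11H12.8 (chromosome IV, 654852 to 655022) and of cdc-48.1, an AAA ATPase of protein degradation (chromosome II, 10563478 to 10563645), followed with 445 and 403.

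The other 4 of the 10 highest peaks were outside promoters. The peak of signal 573 on chromosome V (1151396 to 1151646) lies within the noncoding gene linc-128, 4740 bp upstream of the nearest protein-coding start, that of the calmodulin gene cmd-1. Chromosome IV holds a pair of intergenic peaks downstream of the start of K08F11.1, with signals of 522 (4725517 to 4725699) and 491 (4727944 to 4728131), the latter within 250 bp of a pseudogene. An intergenic peak on X (11094036 to 11094328) had a signal of 483 and lies 4004 bp from the start of W02H3.3.

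Both replicates called many of the same places. Of the 806 peaks of replicate 2, 580 overlapped a peak of replicate 1 by at least 1 bp, a share of 72.0%, while random placements gave 0.496% on average (permutation test, one-sided, p = 0.001, the smallest the placements can give). Of all main peaks, 35.6% overlapped peaks of both replicates' own sets and 34.8% of neither. Among the 410 with the highest signal 94.6% overlapped both, against 1.71% among the 409 with the lowest, of which 84.6% overlapped neither. Across the 1603 main peaks with a region in both replicates, the signals correlated with a Spearman's rho of 0.634 and a Pearson's r of 0.774 on the log2 scale (permutation test, two-sided, p = 1e-05 for both, the smallest possible). These peaks had been selected by their IDR between the same replicates, and over the 23491 ranked regions with a pair of values rho was 0.346. Peaks are not independent replicates, and 34 main peaks had no such pair of values.

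**Figure D1:**
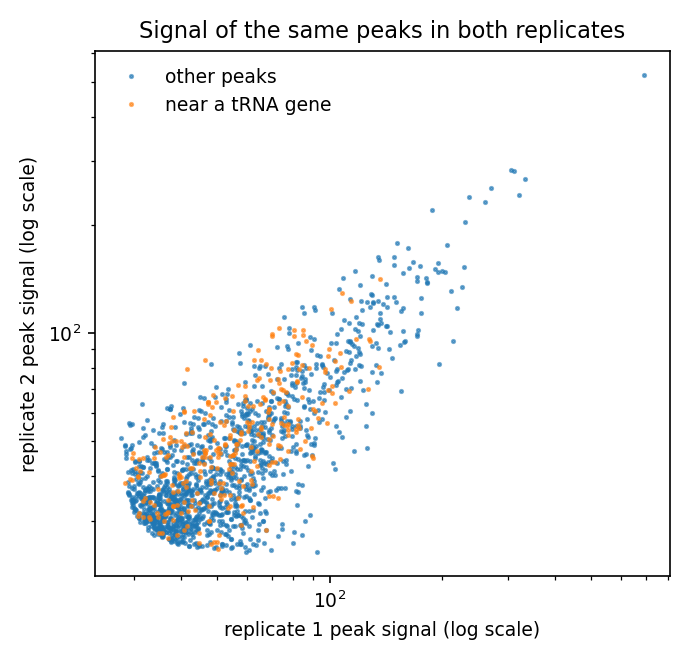
Peak signal (authors' units, log axes) of the same main peaks in replicate 1 and replicate 2, with each point a peak and orange points those within 250 bp of a tRNA gene. The 1603 points rise together with a Spearman's rho of 0.634, and the lin-42 peak stands at the upper right.

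Promoters of protein-coding genes took 785 of the 1637 summits, 48.0% (95% interval 45.5 to 50.4), where random placement gave 25.6%. The enrichment was 1.87-fold (permutation test, two-sided, p = 0.0002, the smallest possible). Replicate 1 alone gave 50.2% and replicate 2 alone 47.3%. Within this promoter window the summits had a median position of -243 bp from the start. Exons were avoided, with 5.62% of summits against 21.6% by chance (permutation adjusted p = 0.00025), and introns held 19.9% against 27.5% (adjusted p = 0.00025). Of the 326 intron summits, 129 were within 250 bp of a tRNA gene. Noncoding genes outside these classes took 8.19% against 3.22%, and intergenic sequence 18.3% against 22.002%. Each summit was counted in the first class that held it, promoters first. The promoter excess by itself therefore lowers the shares of the later classes. The lower intron and intergenic shares do not show that such sequence was avoided, and shares among summits outside promoters were not tested.

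Genes for tRNAs, the adaptors of translation transcribed by RNA polymerase III, were the most enriched class of noncoding gene. Of all summits, 305 lay within 250 bp of a tRNA gene, 18.6% (95% interval 16.8 to 20.6) against 0.361% by random placement, a 51.6-fold enrichment (permutation test, two-sided, adjusted p = 0.000333). The enrichment was 275-fold inside the gene and 16.8-fold within 1000 bp. The share was 21.1% in replicate 1 and 24.1% in replicate 2. At these peaks the summit lay at a median of 18 bp into the gene from its 5′ end, while tRNA genes had a median length of 72 bp. Of the 612 tRNA genes, 341 had a summit within 250 bp, 55.7%, against 38.6% in replicate 1 alone and 36.4% in replicate 2 alone.

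Genes for small nucleolar RNAs, which guide modification of other RNAs, and small nuclear RNAs, which act in splicing, were also enriched. Summits within 250 bp of a snoRNA gene made up 4.28% (19.99-fold) and of a snRNA gene 1.16% (16.9-fold), each with an adjusted p of 0.000333. The snoRNA enrichment was 31.7-fold in replicate 2 alone, 32.9-fold in the upper 50% of peaks by signal and 10.3-fold inside the gene, and within 1000 bp it was 7.93-fold and that of snRNA genes 5.56-fold, all past the threshold. For miRNA genes 9 summits gave a 3.73-fold enrichment (permutation adjusted p = 0.00143), and genes annotated as ncRNA held 425 summits, 26.0% against 4.24% by chance (permutation adjusted p = 0.000333), of which 197 also lay near a tRNA gene. The ncRNA enrichment of 6.13-fold was 15.3-fold inside the gene and 2.70-fold within 1000 bp. Antisense RNA genes, with 6 summits, did not pass (2.60-fold, permutation adjusted p = 0.0742), but they did within 1000 bp (2.24-fold, adjusted p = 0.0420) and with promoters left out (5.52-fold, adjusted p = 0.0030), and lincRNA genes did not (1.07-fold, adjusted p = 1). Pseudogenes (0.450-fold) and piRNA genes (0.230-fold) held fewer summits than by chance, each with an adjusted p of 0.000333. Counting only summits inside the gene, miRNA genes held 1 summit (2.28-fold, permutation adjusted p = 0.884) and piRNA genes 0 (adjusted p = 0.0933), so neither passed. Within 1000 bp both passed with values nearer to chance, 2.12-fold and 0.594-fold. No summit lay near the 20 annotated rRNA genes, which allows a share of up to 0.183%, taken as 3 of 1637 summits. This lies above the 0.0156% given by chance, so depletion was not detectable.

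**Figure D2:**
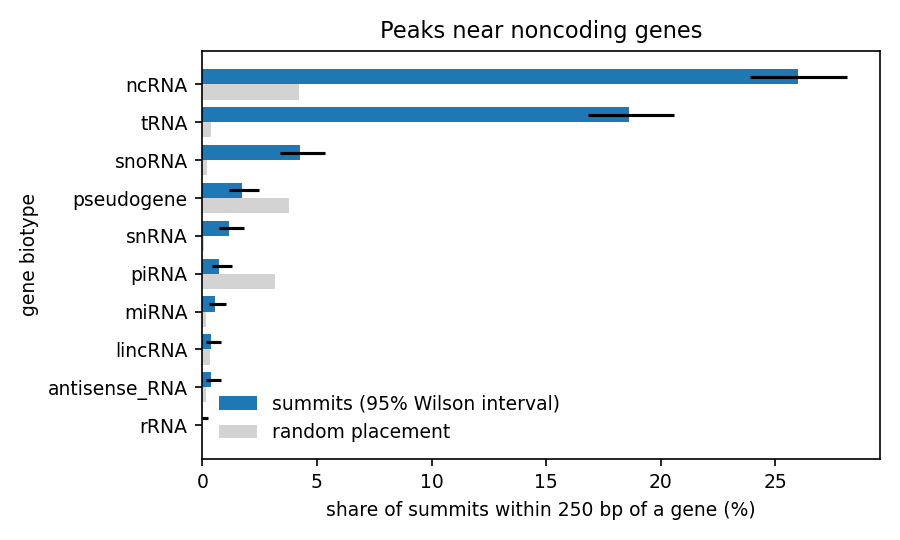
Share of main summits (percent) within 250 bp of genes of each noncoding biotype, with 95% Wilson intervals, beside the share under random placement. The tRNA bar stands at 18.6% against 0.361% by chance, while the pseudogene and piRNA bars fall below theirs.

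**Figure D3:**
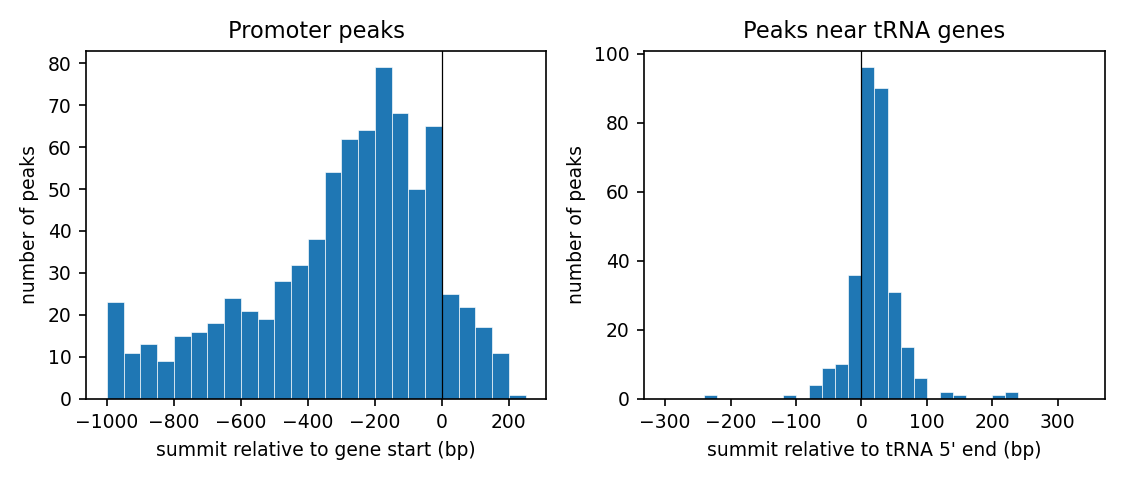
Number of peaks by distance of the summit (bp). The left panel holds only the 785 promoter peaks, by distance from a protein-coding start in 50 bp bins. Its range is set by the promoter window. The right panel holds the 305 peaks near tRNA genes, by distance from the 5′ end of the gene in 20 bp bins. Promoter summits have a median position of -243 bp, and tRNA summits gather within the gene at a median of 18 bp.

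Of 19973 protein-coding genes, 941 were bound. Of the fixed lists, 7 were bound more often than other genes and 4 less often. No library without the tag was analysed here. Binding at these promoters therefore cannot be told apart from pull-down at open or strongly transcribed loci without the tagged protein. Among the 81 ribosomal protein genes 26 were bound, 32.1% against 5.73% of other genes, an odds ratio of 7.77 (95% interval 4.64 to 12.7; Fisher's exact test, two-sided, adjusted p = 4.70e-12). The strongest were rpl-3, rpl-15, rpl-35 (signal 356) and rpl-20 (signal 331). Chaperone genes, whose products fold proteins, had 20 of 65 bound, an odds ratio of 7.25 (4.03 to 12.6, Fisher's exact adjusted p = 2.94e-09), led by cct-8 (signal 254), dnj-28 (224), dnj-13 (220) and hsp-3 (217), the last an endoplasmic reticulum chaperone of the BiP type. The chromatin regulators had 20 of 90 bound, an odds ratio of 4.65 (2.66 to 7.79, Fisher's exact adjusted p = 1.04e-06). Their strongest members were lin-54, a DNA-binding part of the DREAM complex (signal 289), set-16, an MLL-type histone methyltransferase (256), set-21 (242) and cbp-1, a CBP/p300 acetyltransferase (201).

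Lists for splicing, oxidative phosphorylation, translation and the vacuolar ATPase were past the threshold with fewer bound genes. Splicing had 10 of 42 (odds ratio 5.02, Fisher's exact adjusted p = 0.000522), with prp-19 at a signal of 248 and snr-1 at 124, while rsp-1 and rsp-2 share the summit of signal 123. Oxidative phosphorylation had 8 of 45 (odds ratio 3.46, Fisher's exact adjusted p = 0.0134), led by the cytochrome c oxidase subunit genes cox-5A (signal 308), cox-5B (225), cox-6A (149) and cox-6B (138). Translation factors and tRNA synthetases had 10 of 73 (odds ratio 2.54, Fisher's exact adjusted p = 0.0253), with iff-2 at 239, eef-1G at 165, eif-3.C at 144 and eef-2 at 140. Vacuolar ATPase genes had 6 of 20 (odds ratio 6.85, Fisher's exact adjusted p = 0.00275), with vha-1 at 113, vha-2 at 88.9, vha-8 at 86.7 and vha-13 at 79.7. The vacuolar ATPase call was lost in the upper 50% of peaks by signal (odds ratio 1.45, Fisher's exact adjusted p = 0.736) and in each replicate's own set, with odds ratios of 2.63 in replicate 1 (Fisher's exact adjusted p = 0.424) and 1.63 in replicate 2 (adjusted p = 0.645). In replicate 2 alone, splicing (odds ratio 2.39, Fisher's exact adjusted p = 0.385) and translation (1.80, adjusted p = 0.468) were also not called, and neither was oxidative phosphorylation, whose odds ratio of 3.90 was no lower (Fisher's exact adjusted p = 0.0517). A further setting assigned only the nearest start to each peak, at any distance, so peaks outside promoters also counted. The bound share of genes outside the splicing list was 7.91% there, against 5.86% with the promoter window. In that setting splicing, translation and oxidative phosphorylation were not called, with odds ratios of 2.33, 1.64 and 2.14 (Fisher's exact adjusted p = 0.137, 0.356 and 0.208). The odds ratios fell to 3.36 for ribosomal proteins, 3.22 for chaperones and 2.94 for chromatin regulators. These changes are not the effect of shared promoter peaks alone. Among genes with a ranked region, translation had an odds ratio of 2.05 and was not called (Fisher's exact adjusted p = 0.139). Proteasome genes, with 2 of 33 bound (odds ratio 1.02, Fisher's exact adjusted p = 1), and mitochondrial ribosomal protein genes, with 6 of 70 (1.49, adjusted p = 0.493), did not pass.

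The lists bound less often were chemoreceptors, innate immunity, neuronal genes and cuticle collagens. Chemoreceptor genes had 4 of 1309 bound, an odds ratio of 0.0427 (0.0116 to 0.110, Fisher's exact adjusted p = 1.45e-29), namely srh-269 with a signal of 176, sre-23 with 165, srh-2 and srm-3. Innate immunity and detoxification genes had 6 of 641 (odds ratio 0.142, Fisher's exact adjusted p = 5.20e-10), among them clec-126, gst-27, cyp-43A1 and gst-9. Neuronal genes had 4 of 206 (odds ratio 0.310, Fisher's exact adjusted p = 0.0253), namely the insulin-like gene ins-39 with a signal of 218, flp-23, elks-1 and nlp-33, and cuticle collagens had 3 of 174 (odds ratio 0.275, adjusted p = 0.0303), namely col-185, col-71 and bli-1. Both of the last calls were lost in several settings in which the odds ratios stayed at or below 0.398. These were all protein-coding genes as the background (neuronal 0.398 and collagens 0.353, Fisher's exact adjusted p = 0.151 for each), replicate 2 alone (0.148 and 0.355, adjusted p = 0.0801 and 0.439), strata of the upstream gap (0.349 and 0.281, adjusted p = 0.0986 and 0.0726) and, for collagens, the upper 50% by signal (0.157, adjusted p = 0.0804). With only the nearest start, at any distance, the odds ratios themselves rose, to 0.649 for neuronal genes (Fisher's exact adjusted p = 0.356) and 1.09 for collagens (adjusted p = 0.897). That of collagens also rose with a window of 2000 and 500 bp (0.761, Fisher's exact adjusted p = 0.682). None of the 53 major sperm protein genes was bound (Fisher's exact adjusted p = 0.149), and nuclear hormone receptors had 11 of 269 bound (odds ratio 0.671, adjusted p = 0.409). With the window of 2000 and 500 bp both were past the threshold as bound less often, with 0 of 53 (Fisher's exact adjusted p = 0.0446) and an odds ratio of 0.522 (adjusted p = 0.0467). The remaining lists did not pass, among them molting and epidermis with 4 of 82, whose bound members include the heterochronic regulators lin-28 (signal 189) and lin-14 (74.7), and histones with 3 of 72, led by his-37 (311). Muscle genes (0.720), vitellogenins and intestine (0.616), homeobox and bHLH factors (0.726) and germline genes (1.09) also did not pass.

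**Figure D4:**
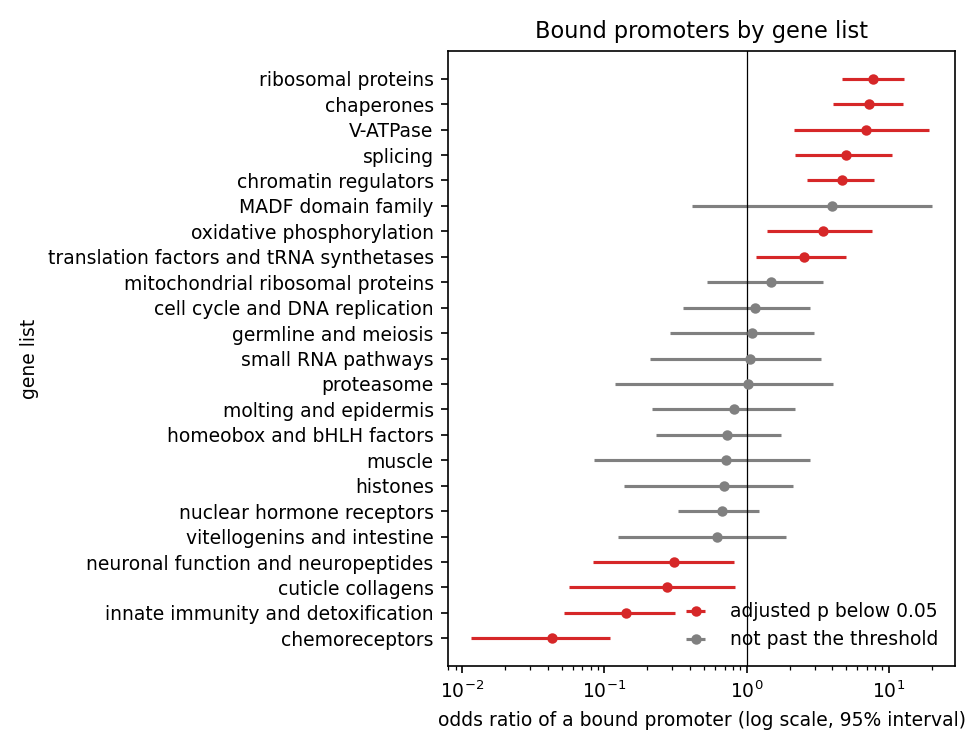
Odds ratio (log axis) of a bound promoter for members of each gene list against other genes with a class symbol, with 95% intervals and red for lists past the threshold. Ribosomal proteins (7.77) and chaperones (7.25) lie highest and chemoreceptors (0.0427) lowest, and the sperm list with 0 bound genes is not drawn.

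Chromosome X and chromosome III held more peaks than their length gives. On X there were 386 peaks, 23.6% (95% interval 21.6 to 25.7) against 17.7% of the length, and on III 280, 17.1% against 13.7% (multinomial permutation draws, two-sided, adjusted p = 0.0004 for both). Chromosome V held 221 peaks, 13.5% against 20.9% (permutation adjusted p = 0.0004), and IV 242, 14.8% against 17.4% (adjusted p = 0.00690). With gene number as the background X was given 13.7%, and its enrichment was 1.72-fold (multinomial permutation draws, two-sided, adjusted p = 0.0004). X carries 276 of the 612 tRNA genes, and 149 of its peaks lay near one. Without peaks near tRNA genes X held 17.8% of peaks, still above the share given by gene number. Its excess over its length was no longer past the threshold (permutation adjusted p = 0.931). IV, with 15.7%, was no longer past the threshold either (permutation adjusted p = 0.148). A deficit remained there, at 0.899-fold against 0.847-fold with all peaks. III and V stayed past the threshold with 18.8% and 14.6% (permutation adjusted p = 0.0006 for both). The middle parts of the chromosomes, from 25% to 75% of the length, held 56.0% of summits, against 55.5% given by the genes' own positions (permutation test, two-sided, p = 0.724). Against the 50% given by length the share was 1.12-fold higher (permutation test, two-sided, p = 0.0002, the smallest possible).

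Words that overlap AGACGCAG, and others such as CTGAGCTA, were more frequent at the summits than beside them. On chromosomes I, III and V, 106 of 9600 words were more frequent at the centre than in the flanks. Without peaks near tRNA genes, 55 of 7868 words were. All 10 leading words of the main set passed on chromosomes II, IV and X. AGACGCAG, or CTGCGTCT on the other strand, lay within 50 bp of 59 of 889 summits there, 6.64%, and in the flanks of 11, 1.24% (Fisher's exact test, two-sided, adjusted p = 7.65e-09). GAGACGCA and GACGCAGA, which overlap it, stood at 58 and 40 summits against 11 and 6 flanks. Of 2080 words of 6 bases, 397 were more frequent at the centre on chromosomes I, III and V. The leading ones included CGCGCA, ACGCGC and CGCGGC, and also ACGCAG, a part of AGACGCAG. Base composition was not controlled for, so the word counts do not separate particular words from a general difference in composition. CTGAGCTA was at 50 summits and in no flank (Fisher's exact adjusted p = 8.74e-15), but without peaks near tRNA genes it was at 2 of 678 summits (adjusted p = 0.4996). Its count thus came almost only from peaks near tRNA genes. Of the 612 tRNA genes, 389 have a sequence with over 5 identical copies in the genome. The test chromosomes may therefore repeat sequences of the others and are not an independent test of this word. ACCACTCG, CCACTCGG and ATGGCCGA, also among the 10, were at 30, 31 and 31 of 889 summits. Without peaks near tRNA genes they were at 12, 15 and 17 of 678. They still passed, but the part of their counts near tRNA genes has the same limit. Of the peaks within 250 bp of a tRNA gene, 0 of 305 had AGACGCAG at the centre, much of which the tRNA gene itself can fill. Away from tRNA genes, 64 of 716 promoter peaks had it, 8.94%, and 55 of 616 other peaks, 8.93%.

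**Figure D5:**
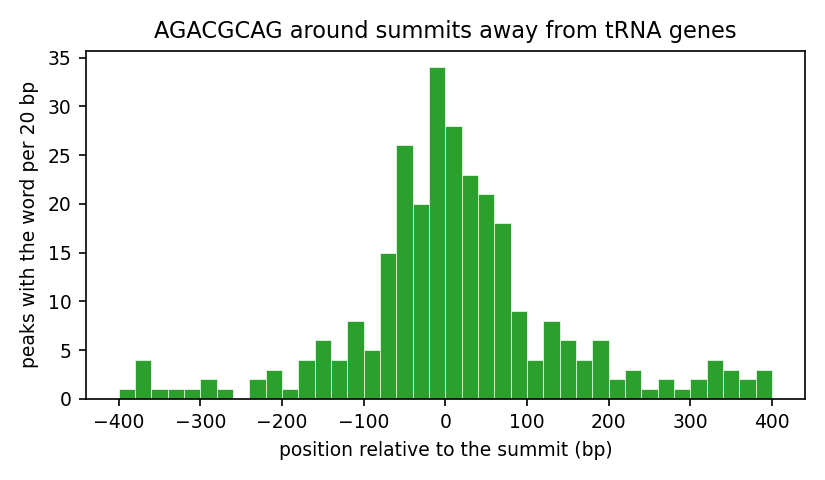
Number of main peaks away from tRNA genes with AGACGCAG on either strand, by position relative to the summit (bp) in 20 bp bins. The counts peak at the summit, where a bin reaches 34 peaks, and fall to a few per bin beyond 200 bp.

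Promoter peaks had a slightly higher median signal than other peaks in the main set, and the difference passed in some settings only. The median was 92.0 against 87.02, a difference of 4.98 (permutation test, two-sided, p = 0.0385). The difference was 0.370 in replicate 1 alone (permutation p = 0.822) and 1.58 in replicate 2 alone (p = 0.277), so neither replicate's own set passed. It did not pass in the upper 50% by signal (1.00, permutation p = 0.774), with a window of 2000 and 500 bp (4.13, p = 0.114) or as mean log2 signal (0.07, p = 0.0819), while it passed with a window of 500 and 100 bp (8.63, p = 0.00026), without peaks near tRNA genes (7.06, p = 0.00117) and in the pooled set (6.35, p = 0.00615).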

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

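The tests of X, and that of tRNA genes with no other within 1000 bp, were chosen only after the result was seen; the others were chosen once the pattern, but not their values, had been seen. In the ranked list between the replicates, 113 regions passed the IDR threshold but were absent from the thresholded set, and they stand out as signal in data that the peak comparisons do not use. Their median signal was 133, against 89.3 for the kept peaks. The strongest, on X from 15810951 to 15811199 with no annotated gene, had a signal of 3467, above the highest kept peak. Of these regions 3 had a summit in a promoter and 0 were near a tRNA gene. A candidate explanation is a fixed list of regions left out of every set. Of the regions 100% overlapped no kept peak of any set, and 91 overlapped a region left out of a replicate's own set. Neither value was set against chance. The kept peaks of the main set cover only 406 kb, so the 100% has little weight by itself. Their soft-masked repeat content was also higher than that of kept peaks, with a difference of medians of 79.5 percentage points (permutation test, two-sided, p = 1e-05, the smallest possible), in line with repeats as a source, and no biological explanation was tested.

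Peaks at tRNA genes could come from reads shared between identical copies, but of tRNA genes whose sequence occurs once in the genome, 41.4% (95% interval 33.6 to 49.7) had a summit within 250 bp, against 1.04% for random regions of that length. In the replicates' own sets the share was lower, 29.3% in replicate 1 and 22.9% in replicate 2, against 0.633% and 0.538% by chance. With no other tRNA gene within 1000 bp it was 37.4% of 99 genes (28.3% and 20.2% in the replicates). Reads shared between fully identical copies are therefore not the whole cause. A gene that differs from others by a single base counted as occurring once, so reads shared between near copies were not tested. Genes with over 5 copies had a higher share, 60.7%, to which shared reads may add, and pull-down at open or strongly transcribed loci without the tagged protein cannot be told apart from binding, because no library without the tag was analysed here; 91.7% of tRNA genes had a ranked region, against 44.2% by chance, and no biological explanation was tested.

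The excess of peaks on X over its length may follow from its tRNA genes. Without peaks near tRNA genes the X share was 17.8% (95% interval 15.8 to 19.9), which includes the 17.7% of the length. This interval still lies above the 13.7% given by gene number, so tRNA genes do not account for the excess over that background. For more signal of any kind on X, the regions that did not pass were counted, and 18.3% of them lay on X. This is below the interval of all main peaks (21.6 to 25.7), so those regions had no X share as high. The count measures no signal, so it does not decide whether signal was higher on X. No biological explanation was tested.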

How the results depend on the processing

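Alternatives on peaks near tRNA genes, other IDR thresholds, all protein-coding genes, ranked partner regions, promoters left out and the same words in other sets were chosen after seeing the data. Of 222 alternative values, 186 kept their direction and side of the threshold or stayed within 1.5 times. The number of peaks was 3125 at an IDR of at most 0.05 and 726 at 0.001, and the replicates' own sets ranged from 806 to 1002. Those sets come from IDR runs with other inputs, and the cause of their smaller size was not tested. Promoter share, shared peaks, replicate correlation and tRNA enrichment kept their direction and side of the threshold in every setting run, but not their size: rho was 0.346 over all ranked regions, and the tRNA enrichment went from 16.8-fold within 1000 bp to 275-fold inside the gene. In each setting 8 to 10 of its own 10 leading words passed; these words differ between settings. The 10 words of the main set passed in the pooled set, the upper 50% by signal and each replicate's own set, and 9 of them without peaks near tRNA genes. The X enrichment of 1.33-fold fell to 1.01-fold without peaks near tRNA genes. With gene number as the background it was 1.72-fold (multinomial permutation draws, two-sided, adjusted p = 0.0004). The share in the middle of chromosomes, 1.01-fold against genes, was 0.994 in the pooled set, 0.980 in the upper 50% by signal and from 0.975 to 1.01 with a replicate left out, none past the threshold, but 1.18-fold against ranked regions that do not pass (Fisher's exact test, two-sided, p = 1.99e-11), of which 47.6% lay there. The number of lists bound more often was 7, and it was 6 in the upper 50% by signal and among genes with a ranked region, 4 with only the nearest start and from 3 to 6 with a replicate left out; the cause was not tested. The odds ratio of cuticle collagens turned to 1.09 with the nearest start only, at any distance. The cause was not tested. The signal difference of 4.98 passed at 6.35 in the pooled set (permutation p = 0.00615). It also passed at 8.63 with a window of 500 and 100 bp (permutation p = 0.00026) and at 7.06 without peaks near tRNA genes (permutation p = 0.00117). It did not pass in the upper 50% by signal (1.00), with a window of 2000 and 500 bp (4.13) or as mean log2 signal (0.0663). With a replicate left out it was from 0.370 to 1.58 and did not pass, and the cause was not tested. No paired analysis was possible because there is 1 group. The unknown depth limits which weak regions could pass.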

Other observations

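The tests in this part were chosen after the tRNA genes and the leading word had been seen, and their values had not. Small RNA genes other than tRNA genes also lay near strong peaks; these genes were picked after their values were seen, by their signal within each kind. Of genes annotated as snRNA, sup-6 on chromosome II had the highest summit, with a signal of 324. The spliced leader RNA gene sls-2.1, whose product is joined to the start of many worm mRNAs, had a summit of signal 321 on chromosome II, R07E5.16 on chromosome III had 254, and sls-2.2 and sls-2.4 had 234 and 205. The snoRNA genes F59C6.15 on chromosome I and ZK994.7 on chromosome V had summits of signal 324 and 280, which lay 76 and 18 bp upstream of the 5′ ends. Near miRNA genes the strongest summit, at mir-52 on chromosome IV, had a signal of 175 at -197 bp from the 5′ end of the gene.

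The share of tRNA genes with a summit may differ between isotypes, the groups that carry the same amino acid (permutation test of the spread over 21 isotypes, p = 0.00110). Cysteine (11 of 13), glycine (42 of 55, 76.4%), aspartate and glutamine (20 of 27 each) stood highest. Among isotypes with at least 12 genes, asparagine and histidine (7 of 20 each, 35.0%) and arginine (17 of 44, 38.6%) stood lowest, and the 1 selenocysteine gene had no summit. Genes in a cluster can share a summit and copies share sequence, so the genes are not independent and this p is too small.

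The word AGACGCAG was hypothesised to mark promoter peaks or strong peaks. Away from tRNA genes it was at 8.94% of promoter peaks and 8.93% of other peaks, an odds ratio of 1.00 (Fisher's exact test, two-sided, p = 1). The median signal was 90.3 with the word and 85.8 without, a difference of 4.46 that did not pass (permutation test, two-sided, p = 0.245). Neither hypothesis gained from these tests, and neither is excluded. In the main set, 24 peaks had a signal below 23.3, the median of the regions that do not pass.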
